A study of Mus musculus with 12 samples.

How the data were processed

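RNA of 12 libraries of 3T3-L1 cells was sequenced by the submitters, 3 libraries in each of 4 groups, all taken on day 6; groups and replicate numbers were read from the sample titles. The treatment text is the same on every sample, the untreated ones included, so the untreated group rests on its title and treatment label. The deposited table holds raw counts per gene, which the authors made with featureCounts 1.5.0-p3, per the submitters' processing notes; CASAVA 1.8.2 is named there too, and the aligner is not given in the sources used here. The authors also deposited FPKM values, which were not used for any test because counts were at hand. Log2 fold changes and p-values of the authors' own comparisons stand in the same deposited table, with the tool not given in the sources used here. The notes name the build mm9, but 98.3% of the gene start and end positions in the table equal those of GENCODE M21 on GRCm38, so coordinates are given as GRCm38. All 27 date-like gene symbols, changed by a spreadsheet, were restored through their gene identifiers. Whether counting used strand is not given, and the library kit named in the labels does not mark strand, so antisense and overlapping genes cannot be separated.

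The table held 54532 genes, 25496 of them with 0 counts in all libraries. Library totals ran from 14522182 to 19436796 counts. Counting intervals and the floor of 3 counts cover counting error only. No pair of replicates agreed within sampling noise (chi-square per gene at least 2.78).

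Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr (14855), scaled by TMM, and fitted by the quasi-likelihood method with 1 term per group over all 12 libraries, which share one estimate of the spread. P-values were adjusted by Benjamini-Hochberg within each of 4 comparisons, with 0.05 as the threshold. The 24 gene lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation, with ranks and with fry. CPM are counts scaled to library totals adjusted by TMM. The axis position projects each library's log2 CPM (prior count 2) on the difference between the DMI and untreated means. Unchanged groups were simulated 1000 times against the DMI libraries.

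The comparisons, tests, lists, alternatives and naming rule were fixed before the data were examined, apart from the alternatives given as chosen after seeing the data. Named genes are a panel of 16 adipocyte genes, the up to 8 largest rises and falls per comparison among protein-coding genes at or above 5 CPM whose replicates do not overlap, up to 4 members of each list that passed, and up to 3 of the most abundant members of a list that did not. In that panel Dlk1 marks preadipocytes and Cyp1b1 is an aryl hydrocarbon receptor target. Panel gene Ucp1 had 0 counts and was not tested.

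Same-numbered libraries deviated together in luteolin and DMI (r = 0.261, 0.337 and 0.59), every pair over 0.1. By this rule the replicate number was treated as a pairing for this comparison. The labels themselves do not say what a number marks, and luteolin library 2 correlated better with DMI library 1 than with DMI library 2. The third library lay lowest on the axis in both groups (0.707 and 0.648). That alone makes libraries 1 and 2 deviate together under either numbering, so these correlations do not show which of them pair. The other comparisons did not meet this rule.

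The fit was tested on simulated data for luteolin with DMI against DMI: in 10 draws over the 14855 genes, 200 genes were changed. It called 13.6% of genes changed 1.5-fold, 69.6% at 2-fold, 98.4% at 4-fold and 100% at 8-fold, and 112 of 1520 calls (7.4%) were genes that had not been changed, somewhat above the threshold. The simulation gave every group the same spread, unlike the real libraries. It also changed 200 genes per draw, while the real comparison called 3, and more changed genes ease the adjusted threshold. The shares called are therefore not the power of the real comparison. In the real fit without pairing Mgll, lower by more than 4-fold (45.7 CPM with DMI, 8.71 with luteolin added), was not called. A group set at 0.6 on the axis was recovered at 0.582.

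Alternatives were RLE scaling, library totals only, no low-count filter, 1 CPM in 3 libraries, protein-coding genes only, DESeq2 1.42.0, limma-voom, only the 6 libraries of a pair, the replicate block, other prior counts, and leaving out each library. By the authors' deposited table, 5192 genes pass 0.05 for DMI against untreated, 61 for luteolin, 365 for quercetin against DMI and 16 between the compounds; of the calls made here, 3860, 3, 119 and 0 are among them, all with the same sign.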

Results

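The data were gene counts from bulk RNA sequencing of mouse 3T3-L1 cells, a fibroblast-like line that turns into fat-storing adipocytes when given a hormonal cocktail. All 12 libraries were taken on day 6 and formed 4 groups of 3: untreated cells, cells given the cocktail of dexamethasone, IBMX and insulin (DMI), and cells given DMI with luteolin or DMI with quercetin. Luteolin and quercetin are plant polyphenols that differ by 1 hydroxyl group, at the position that makes quercetin a flavonol and luteolin a flavone. The labels give neither the doses nor the exposure times of the compounds, so the responses below are side by side and not at doses known to match. Total counts per library ran from 14522182 to 19436796, and 14855 genes passed the low-count filter. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these libraries only. That spread was estimated over all 12 libraries together. The untreated libraries varied least, which can make the p-values of the compound comparisons too small.

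The first comparison, DMI against untreated, shows what induction did by day 6. Fabp4, a fatty acid carrier, went from 3.66 to 2565 CPM (698-fold, log2 fold change 9.45, SE 1.04, adjusted p = 0.000164 by edgeR's quasi-likelihood test, n = 3 per group). Adipoq, which encodes the hormone adiponectin, rose 1480-fold (adjusted p = 0.000126), and the lipid droplet coat gene Plin1 rose 1210-fold (adjusted p = 0.000143). The adipogenic regulators Pparg and Cebpa rose 11.7-fold and 21.3-fold, while Cebpb stood at a log2 fold change of 0.52 (SE 0.26, adjusted p = 0.163). Dlk1, a preadipocyte marker, fell 3.17-fold (adjusted p = 0.00278). Across all genes 4024 changed, 2187 up and 1837 down, of which 1926 changed at least 2-fold.

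Several genes had no count in any untreated library, so their rises are lower bounds against a floor of 3 counts over the group. Pck1, a gluconeogenic and glyceroneogenic enzyme, was at least 742-fold higher with DMI, the sulfate transporter gene Slc13a4 at least 514-fold, the amino acid transporter gene Slc36a2 at least 473-fold, the beta-3 adrenergic receptor gene Adrb3 at least 367-fold and Aatk at least 365-fold. Mrap had 2 counts in the untreated group, and its ratio was 3069 (95% counting interval 849 to 25350). Among the genes with the largest falls, 3 encode antiviral oligoadenylate synthetases, Oas1g (12.3-fold), Oas1a (10.5-fold) and Oas2 (8.31-fold). Oas1a and Oas1g are close paralogs, so the split of counts between them is uncertain. The collagen gene Col14a1 fell 12.6-fold.

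By group, all 22 measured mature adipocyte markers rose, with a median log2 fold change of 9.42 (9.18 with the 3 members at 0 counts set to their bound; adjusted p = 1.96e-37 by camera, adjusted p = 0.131 with an estimated correlation). All 21 oxidative phosphorylation subunits rose (median 1.46, adjusted p = 0.178 with an estimated correlation), Uqcrfs1 by 4.27-fold and Cycs by 7.39-fold. Of 19 fatty acid oxidation genes 18 rose (adjusted p = 0.156 with an estimated correlation), among them Hadhb at 6.21-fold and Acads at 5.08-fold. In the lipogenesis and triglyceride synthesis list 17 of 22 rose and 1 fell (adjusted p = 0.131 with an estimated correlation); Scd1, the stearoyl-CoA desaturase, rose 68.1-fold, Dgat2, an enzyme of triglyceride synthesis, 174-fold and Fasn, the fatty acid synthase, 3.83-fold. Of 13 glucocorticoid response genes 9 rose (adjusted p = 0.0715 with an estimated correlation), with Zbtb16 at 159-fold and Errfi1 at 2.99-fold. Of 20 interferon response genes 17 fell (median -1.39, adjusted p = 0.167 with an estimated correlation), Oasl2 by 3.89-fold and Usp18 by 3.18-fold. Of 22 preadipocyte and extracellular matrix genes 16 fell and 1 rose (adjusted p = 0.185 with an estimated correlation), and Thy1 and Pdgfrb fell 2.80-fold and 2.32-fold. The counts adjusted over the list alone were the same for these 7 lists, except 3 falls in lipogenesis and 2 rises in the matrix list.

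Camera passed 10 further lists, none of which passed with an estimated correlation in the same fit (smallest adjusted p = 0.143). Rises outnumbered falls among adipogenic transcription factors (9 and 2 of 18, Nr1h3 up 24.5-fold), insulin and IGF signalling (10 and 2 of 15, Pde3b up 28.3-fold and Igfbp5 down 6.04-fold), glycolysis and hypoxia (9 and 1 of 17, Bnip3 up 6.09-fold) and NRF2 antioxidant targets (8 and 1 of 19, the catalase gene Cat up 4.59-fold). The same held for brown and beige adipocyte markers (6 and 1 of 8), cholesterol synthesis (9 and 0 of 24, Insig1 up 2.24-fold) and aryl hydrocarbon receptor targets (2 and 0 of 7). Falls outnumbered rises among contractile and serum response genes (9 and 0 of 15, Actn1 down 2.10-fold), lysosome and autophagy genes (8 and 2 of 19, Ctsd down 1.54-fold) and cell cycle genes (9 and 2 of 26, Mcm2 down 1.62-fold). Adjusted over the list alone the counts differed in 6 of these lists: 3 insulin, 10 contractile, 11 lysosome and 10 cell cycle falls, and 10 NRF2 and 3 aryl hydrocarbon receptor rises. Without the third library of each induced group 3 of the 17 lists passed with one. The aryl hydrocarbon receptor call ended without untreated replicate 3 (adjusted p = 0.0512) or quercetin replicate 3 (0.057).

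The other 7 lists did not pass camera. Rises and falls were 3 and 7 of 19 among ATF4 and endoplasmic reticulum stress genes (adjusted p = 0.0884), 3 and 6 of 16 among inflammatory genes (0.492), 0 and 4 of 14 among p53 targets (0.0702) and 1 and 4 of 13 in Wnt signalling (0.323). They were 1 and 4 of 6 among osteoblast and chondrocyte markers (0.0596), 2 and 1 of 4 among muscle cell markers (0.347) and 0 and 2 of 6 among macrophage, endothelial and epithelial markers (0.338). The inflammatory and Wnt lists had medians below 0 (-0.60 and -0.21) and means above it (0.21 and 0.02). Adjusted over the list alone there were 4 ATF4 rises, 2 Wnt rises and 3 falls among the macrophage, endothelial and epithelial markers. Ucp1, the marker of heat-producing brown adipocytes, had no count in any library.

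The count of changed genes fell to 2407, 2441 and 2456 without untreated replicate 1, 2 or 3 and to 1936 and 1865 without DMI replicate 1 or 2. The third DMI library carried the lowest adipocyte gene levels of its group, with Fabp4 at 840 CPM against 2958 and 3896, and mitochondrial transcripts took 2.88% of its counts against 4.72% and 4.28%. The third luteolin library was like it (2.91% against 4.41% and 4.73%), while in the quercetin group the third library had the highest share (4.65% against 3.29% and 3.92%). Without the third library of each induced group, chosen after seeing their adipocyte gene levels, 7970 genes were called, 1566 for luteolin, 5049 for quercetin and 2081 between the compounds; that choice leaves 2 libraries per induced group and narrows the spread by construction.

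**Figure D1:**
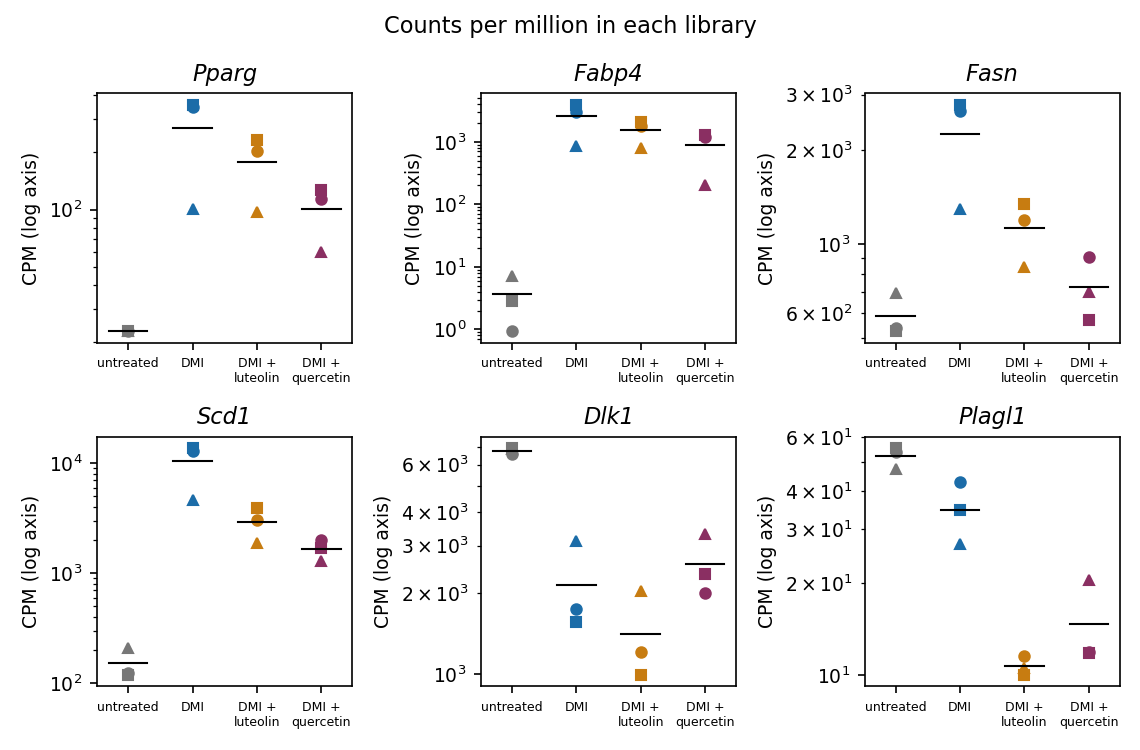
CPM (log axes) of 6 genes in each of the 12 libraries, by group; circles, squares and triangles are replicates 1, 2 and 3, and lines are means of 3. Scd1 averaged 10370 CPM with DMI, 2949 with luteolin added and 1659 with quercetin added.

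The second comparison set luteolin with DMI against DMI alone, which bears on how luteolin alters adipogenic differentiation, the subject the submitters name. In the fit without pairing only 3 genes passed, all lower with luteolin. With the replicate number as a block 25 passed, as given below. Plagl1, an imprinted zinc finger gene (ENSMUSG00000019817) on chromosome 10 (13060504 to 13131694, GRCm38), fell 3.25-fold from 34.8 ± 8.0 to 10.7 ± 0.758 CPM (SD, n = 3; log2 fold change -1.70, SE 0.22, adjusted p = 0.0357 by edgeR). Gfra1, a receptor gene for the neurotrophic factor GDNF (ENSMUSG00000025089) on chromosome 19 (58235604 to 58455909), fell 2.31-fold (adjusted p = 0.0433). H19, an imprinted long noncoding RNA (ENSMUSG00000000031) on chromosome 7 (142575529 to 142578143), went from 18.8 to 4.92 CPM (log2 fold change -1.93, SE 0.24, adjusted p = 0.0299); the naming rule takes protein-coding genes, and H19 is named after its values were seen. Gfra1 and H19 had also fallen with DMI against untreated, so with luteolin they lay farther from the untreated level of 54.8 and 38.5 CPM.

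No adipocyte panel gene passed with luteolin in the fit without pairing. The lowest relative levels in the panel were those of Scd1 (log2 fold change -1.81, SE 0.39, adjusted p = 0.364), Slc2a4, the insulin-responsive glucose transporter gene (-1.69, SE 0.55, adjusted p = 0.617), and Cidec (-1.50, SE 0.77, adjusted p = 0.854). Pparg stood at -0.59 (SE 0.42, adjusted p = 0.943) and Fabp4 at -0.72 (SE 0.71, adjusted p = 0.994). With the replicate block over all 12 libraries none of the 15 tested passed either, the smallest adjusted p being 0.0864 for Slc2a4. With the block in only the 6 libraries, added after seeing the data, 10 passed. Among them were Scd1 (log2 fold change -1.72, adjusted p = 0.000291), Fasn (-0.94, adjusted p = 0.00136) and Pparg (-0.49, adjusted p = 0.0388). The preadipocyte marker Dlk1, which had fallen with DMI, was also lower with luteolin in that fit (-0.594, adjusted p = 0.00285 by edgeR). Without pairing, 5 passed without a low-count filter, 3 without DMI replicate 3, 10 without the third library of each induced group and 1, Scd1, with DESeq2. Dlk1 and Cyp1b1 were among the 10 that passed without the third libraries.

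Of the 24 lists 15 passed camera with luteolin and none of them with an estimated correlation in the same fit without the block, and no list held a member called over all genes. Without the third library of each induced group 8 of the 15 passed with an estimated correlation (adjusted p from 0.042 to 0.0445), lipogenesis and mature adipocyte markers among them. That choice was made after seeing the data and narrows the spread by construction. With fry, which tests whether the genes of a list move on balance one way, 0 of the 15 passed. The lipogenesis list had a median of -0.59 (adjusted p = 8.82e-14 by camera, adjusted p = 0.146 with an estimated correlation), and 7 of its 22 members were lower adjusted over the list alone. Its member Mgll, a monoglyceride lipase gene and not one of synthesis, stood at -2.39 and Thrsp at -1.79, neither past the threshold over all genes. Mature adipocyte markers had a median of -0.87 (1 lower adjusted over the list alone, adjusted p = 0.332 with an estimated correlation). Lower as well by camera were fatty acid oxidation (-0.53), oxidative phosphorylation (-0.32), brown and beige markers (-0.91), cholesterol synthesis (-0.29), glycolysis and hypoxia (-0.55), insulin and IGF signalling (-0.28) and adipogenic transcription factors (-0.18), with adjusted p from 0.146 to 0.485 with an estimated correlation. Higher were contractile and serum response genes (0.31), inflammatory genes (0.36), p53 targets (0.17), osteoblast and chondrocyte markers (0.20) and lysosome and autophagy genes (0.14), with adjusted p from 0.146 to 0.429 with an estimated correlation. Adjusted over the list alone, 2 glycolysis, 1 brown and beige and 1 insulin gene were lower and 1 inflammatory gene was higher. Interferon response genes had a median of -0.59 (5 of 20 lower adjusted over the list alone, adjusted p = 0.262 with an estimated correlation), with Mx1 at -1.15 and Gbp2 at -0.74, but the median was -0.05 without DMI replicate 3 (adjusted p = 0.723 by camera) and 0.03 without the third library of each induced group (adjusted p = 0.805).

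Single libraries also ended the camera calls of adipogenic transcription factors (without DMI replicates 1 or 2 or luteolin replicate 3, adjusted p = 0.155, 0.312 and 0.14), oxidative phosphorylation (DMI replicate 2 or luteolin replicate 3, 0.351 and 0.14), osteoblast and chondrocyte markers (DMI replicates 1 or 2, 0.0617 and 0.0861) and inflammatory genes (DMI replicate 2, 0.0827). The lysosome call ended without any untreated replicate, DMI replicates 1 or 2, luteolin replicate 3, or quercetin replicates 1 or 3 (0.0505 to 0.448). The 9 lists that did not pass (adjusted p from 0.0606 to 0.916) were macrophage, endothelial and epithelial markers, cell cycle, ATF4, glucocorticoid response, Wnt, matrix genes, muscle markers, NRF2 and aryl hydrocarbon receptor targets. In the Wnt, NRF2 and aryl hydrocarbon receptor lists median and mean lay below 0 while the test pointed up, and adjusted over the list alone 1 Wnt gene was higher, and 1 aryl hydrocarbon receptor target was higher and 1 lower.

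With the replicate number as a block, a pairing inferred from these same data, 25 genes passed, 4 up and 21 down, the same 3 among them. The data do not show how libraries 1 and 2 pair, so the block calls rest on an assumed pairing. The 21 lower ones included Lep, the leptin gene (log2 fold change -3.64, adjusted p = 0.0448), at low levels (2.37 CPM with DMI, 0.179 with luteolin added). Mgll, a monoglyceride lipase gene (-2.28, adjusted p = 0.0204), Pnpla3 (-2.16, adjusted p = 0.0168), Pck1 (-1.87, adjusted p = 0.0128) and the transcription factor gene Klf15 (-1.58, adjusted p = 0.0425) were lower too. So were Cpz, Nrk and Prokr1 (1.77, 2.16 and 5.75 CPM with luteolin added, 7.59, 7.67 and 14.8 with DMI). Their untreated means were higher still (9.37, 12.3 and 28.2 CPM), so with luteolin they lay farther from the untreated level. Ptgs2, which encodes a cyclooxygenase, was among the higher ones (2.10, adjusted p = 0.0168). The block fitted to only the 6 libraries of the pair, an alternative added after seeing the data, called 929 genes, 306 up and 623 down. Adjusted over the list alone, 13 of 22 lipogenesis genes and 9 of 22 mature adipocyte markers were lower under the block over all 12 libraries; with an estimated correlation that block left 1 list past the threshold, brown and beige markers (adjusted p = 0.0322). Without the block 904 of the 14855 genes had an unadjusted p under 0.05, little above the share of 0.05 that unchanged genes alone would give. The unblocked count was 0 with limma-voom, with only the 6 libraries of the pair and among protein-coding genes, 48 with DESeq2 and 363 without a low-count filter. It was 0 without untreated replicate 1, 2 or 3, DMI replicate 1 or luteolin replicate 1, 2 or 3, 1 without DMI replicate 2 or quercetin replicate 1, 6 without quercetin replicate 3 and 259 without DMI replicate 3.

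The third comparison set quercetin with DMI against DMI alone. Scd1 fell 6.25-fold (log2 fold change -2.64, SE 0.41, adjusted p = 0.0273 by edgeR, n = 3 per group), Fasn fell 3.09-fold (adjusted p = 0.042) and Slc2a4 fell 8.87-fold (adjusted p = 0.0443). The largest falls among genes at or above 5 CPM were in Ffar4, a receptor gene for long-chain fatty acids (50.9-fold, adjusted p = 0.0318), Slc36a2 (18.3-fold), Car3 (16.7-fold), the co-receptor gene Klb (16.1-fold), Camp (14.2-fold), Mgll (13.6-fold) and the lactate receptor gene Hcar1 (12.6-fold). The leptin gene Lep, at lower counts, had a ratio of 41.9 between DMI and quercetin libraries (3 counts with quercetin, 95% counting interval 13.96 to 206). Rises were smaller, led by Prl2c2 (3.12-fold, adjusted p = 0.0469), Snrpe (2.10-fold) and Slc9a9 (2.09-fold). Prl2c2 has near-identical neighbours and Snrpe and Rpl39 (1.89-fold) have processed copies in the genome, so these counts are uncertain.

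In all 150 genes changed with quercetin, 24 up and 126 down, and 114 changed at least 2-fold. That balance moved with the libraries: rises and falls were 303 and 272 without quercetin replicate 1, 1089 and 1557 without DMI replicate 3 and 2573 and 2476 without the third library of each induced group. They were 249 and 709 with DESeq2 and 592 and 1145 without a low-count filter. Of the 126 that fell, 103 were among the genes that rose with DMI (18.55 for independent lists), and of the 24 that rose, 9 were among those that fell with DMI (2.97 for independent lists). Both comparisons share the DMI libraries, which can add to such an overlap. Panel genes that did not pass included Pparg (-1.42, SE 0.43, adjusted p = 0.106), Cebpa (-1.55, SE 0.49, adjusted p = 0.113), Fabp4 (-1.52, SE 0.72, adjusted p = 0.246) and Adipoq (-1.50, SE 0.68, adjusted p = 0.227). Of the 3 panel calls only Scd1 passed without untreated replicate 1, 2 or 3 or luteolin replicate 2. No panel gene passed without DMI replicates 1 or 2, luteolin replicate 1 or quercetin replicates 2 or 3, with limma-voom or with only the 6 libraries. DESeq2 passed 5 of 15, and 10 passed without DMI replicate 3, 12 without a low-count filter and 14 without the third library of each induced group.

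Of 22 lipogenesis genes 5 fell with quercetin over all genes and 17 adjusted over the list alone (median -0.98, adjusted p = 1.28e-15 by camera, adjusted p = 0.153 with an estimated correlation), with Pnpla3 down 9.91-fold. Mature adipocyte markers gave 5 of 22 and 17 of 22 (median -1.83, adjusted p = 0.249 with an estimated correlation), with Retn, the resistin gene, down 8.28-fold. Fatty acid oxidation genes gave 0 and 17 of 19 (adjusted p = 0.306 with an estimated correlation), glycolysis and hypoxia genes 2 and 9 of 17 (0.153 likewise, with Egln3 down 2.81-fold), and insulin and IGF signalling genes 2 and 10 of 15, with 1 rise adjusted over the list alone (0.153 likewise, with Pde3b down 5.25-fold). Camera also passed 8 lists that an estimated correlation in the same fit did not (adjusted p from 0.153 to 0.461). Lower were brown and beige markers (median -2.18, 6 of 8 lower adjusted over the list alone), oxidative phosphorylation (-0.73, 0 of 21), cholesterol synthesis (-0.28, 1 of 24) and adipogenic transcription factors (-0.28, 7 of 18, with Klf15 down 8.44-fold). Higher were contractile genes (0.43), lysosome genes (0.30), p53 targets (0.30) and osteoblast and chondrocyte markers (0.56), of which 1 contractile and 1 osteoblast gene were higher adjusted over the list alone. Of all 13 lists that passed camera with quercetin, 8 passed with an estimated correlation without the third library of each induced group (adjusted p from 0.0401 to 0.0414), and 6 passed with fry. Single quercetin libraries ended the camera calls of cholesterol synthesis (without replicate 1, adjusted p = 0.0704), lysosome genes (replicate 2, 0.0847), p53 targets (replicate 2, 0.0592) and osteoblast markers (replicates 1 or 2, 0.0779 and 0.0592).

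The 11 lists that did not pass with quercetin had adjusted p from 0.158 to 0.725 by camera. Interferon response genes had a median of -0.22 (adjusted p = 0.547), which was -0.51 without DMI replicate 2 (adjusted p = 6.57e-05) and 0.50 without DMI replicate 3 (adjusted p = 0.00315). Adjusted over the list alone, rises and falls were 3 and 2 among inflammatory genes, 3 and 4 in glucocorticoid response, 2 and 3 among NRF2 targets, 1 and 2 among aryl hydrocarbon receptor targets, 2 and 0 in Wnt signalling, 2 and 0 among macrophage, endothelial and epithelial markers and 0 and 1 among muscle markers; matrix, cell cycle, interferon and ATF4 lists had none. Over all genes 1 inflammatory gene fell and 1 NRF2 target rose. Median and mean differed in sign for aryl hydrocarbon receptor targets (0.12 and -0.13) and cell cycle genes (-0.003 and 0.03).

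The quercetin count moved with the libraries in the fit, the tool and the filter. The quercetin p-values rest on a spread estimated over all 12 libraries, including the untreated ones, which varied least and are in neither group compared. Median gene SD on the log2 scale was 0.105 in untreated, 0.244 in DMI, 0.173 in luteolin and 0.327 in quercetin libraries, and with only the 6 libraries of the pair 0 genes passed, with limma-voom 1, with library totals only 59, at 1 CPM in 3 libraries 55, among protein-coding genes 50, with DESeq2 958 and without a low-count filter 1737. Leaving out untreated replicates 1, 2 and 3 in turn gave 14, 14 and 13 genes, DMI replicates 0, 0 and 2646, luteolin replicates 9, 21 and 273, and quercetin replicates 575, 1 and 4.

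**Figure D2:**
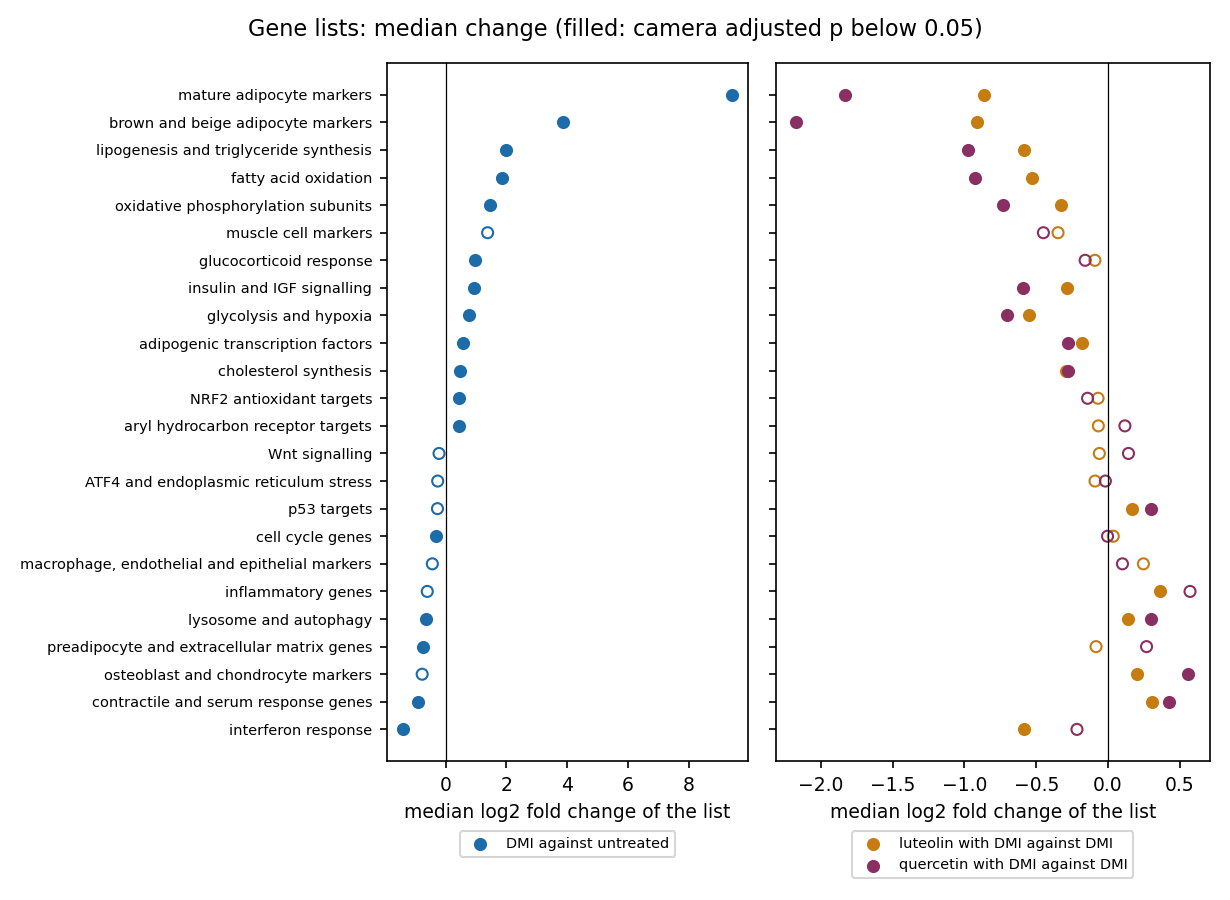
Median log2 fold change of each of the 24 gene lists, for DMI against untreated (left) and for each compound with DMI against DMI (right); filled points passed camera with its preset correlation. Mature adipocyte markers had medians of 9.42, -0.87 with luteolin and -1.83 with quercetin; no filled point passed with an estimated correlation in the same fit.

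Luteolin with DMI was also set directly against quercetin with DMI. No gene passed (0 by edgeR and limma-voom, 1 by DESeq2). By edgeR 1327 of the 14855 genes had an unadjusted p under 0.05, where unchanged genes alone would give a share of 0.05. For Scd1 the log2 difference, luteolin over quercetin, was 0.83 (95% interval -0.004 to 1.67, adjusted p = 0.555), for Fasn 0.64 (0.027 to 1.24, adjusted p = 0.552), for Slc2a4 1.46 (0.244 to 2.68, adjusted p = 0.541) and for Fabp4 0.81 (-0.73 to 2.35, adjusted p = 0.69), intervals too wide to show that the compounds acted alike. By camera, luteolin libraries were higher in mature adipocyte markers (median 1.06), lipogenesis (0.42), oxidative phosphorylation (0.33), fatty acid oxidation (0.37), brown and beige markers (1.03) and insulin and IGF signalling (0.33), and lower in interferon response (-0.44) and matrix genes (-0.21). All 8 were lost with an estimated correlation (adjusted p from 0.619 to 0.631), and adjusted over the list alone 1 insulin gene was lower and no other member of a list passed. The other 16 lists did not pass camera (adjusted p from 0.0645 to 0.941). Median, mean and test differed in sign for inflammatory genes (-0.11, 0.04, up), macrophage, endothelial and epithelial markers (-0.16, 0.02, up), cholesterol synthesis (-0.02, -0.03, up) and ATF4 genes (-0.006, 0.002, down).

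The count of 0 between the compounds became 10 without quercetin replicate 1, 1 without luteolin replicate 3 or quercetin replicate 3 and 450 without a low-count filter. Without quercetin replicate 3 the camera calls of fatty acid oxidation and oxidative phosphorylation ended (adjusted p = 0.229 and 0.382), and those of matrix genes (0.0546 to 0.26) and insulin signalling (0.0757 to 0.202) ended without luteolin replicates 1 or 2 or any quercetin replicate.

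On an axis from the untreated mean at 0 to the DMI mean at 1, built from the 4024 genes changed by DMI, DMI libraries lay at 1 ± 0.255, luteolin libraries at 0.822 ± 0.153 and quercetin libraries at 0.602 ± 0.166 (SD, n = 3). The luteolin mean was 0.694 without DMI replicate 3 and 0.903 without luteolin replicate 3. The quercetin mean was 0.497 without DMI replicate 3 and 0.696 without quercetin replicate 3. Exact two-sided permutation tests gave p = 0.3 for luteolin and p = 0.2 for quercetin against DMI, and p = 0.3 between the compounds, where 0.1 is the smallest p that 3 against 3 allows. Luteolin lay below DMI in all 3 same-numbered pairs (0.885 and 1.117, 0.934 and 1.175, 0.648 and 0.707). The mean paired difference was -0.178 (exact two-sided sign-flip permutation p = 0.25, the smallest that 3 pairs allow). This paired test was added after seeing the data, and the pairing was inferred from them. Among 1000 simulated unchanged groups, drawn without pairing, 13.3% lay at or below the luteolin position and 0.4% at or below the quercetin position. Across genes, which are not independent replicates, the luteolin effect correlated with the DMI effect at r = -0.497 and the quercetin effect at r = -0.736, where shared DMI libraries alone gave a mean of -0.141 (95% of simulations from -0.785 to 0.577). The covariances were -0.246 and -0.54 beside a simulated -0.07, and 16.8% and 2% of simulations lay as low. For the correlations those shares were 28% and 6.9%, and without luteolin replicate 3 the luteolin correlation was -0.319. The luteolin and quercetin effects correlated at r = 0.688 (simulated mean 0.45, 95% of simulations from -0.496 to 0.955), and 36.3% of simulations lay as high. Their covariance was 0.165 beside a simulated 0.06, and 9% of simulations lay as high. Splitting the 3 DMI libraries would leave 1 in a part, so part of each difference from the simulated value may come from the shared controls.

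**Figure D3:**
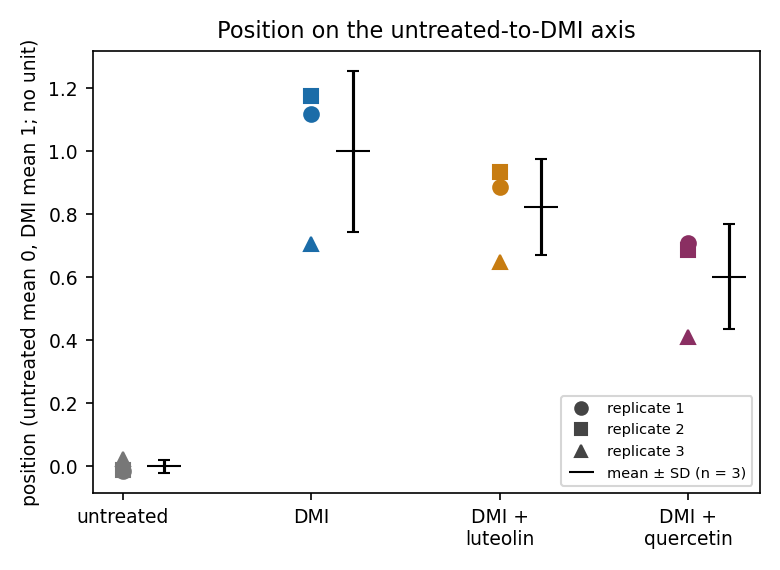
Position of each of the 12 libraries on the untreated-to-DMI axis (no unit), with the mean and SD of 3 beside each group. The third library was the lowest of each induced group, at 0.707 with DMI, 0.648 with luteolin and 0.41 with quercetin.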

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

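The settings that leave out the third libraries, restrict the block to 6 libraries, combine it or them with an estimated correlation, or pair the axis positions were chosen after seeing the data. Effect correlations kept their sign in every setting run. Axis positions kept theirs too, which an axis from untreated at 0 to DMI at 1 nearly ensures for induced libraries. Leaving out each library, the luteolin mean position ran from 0.694 to 0.903 and the quercetin mean from 0.497 to 0.696. RLE scaling moved no count by over 1.5 times. For luteolin, counts of changed genes (and of those changed at least 2-fold) were 363 (217) without a low-count filter, 0 (0) with protein-coding genes, with only the 6 libraries and with limma-voom, 48 (35) with DESeq2, 25 (24) with the replicate block, 929 (227) with the block in 6 libraries and 1566 (318) without the third libraries. For quercetin they were 59 (52) with library totals only, 1737 (728) without a filter, 55 (49) at 1 CPM in 3 libraries, 50 (45) with protein-coding genes, 0 (0) with 6 libraries, 958 (481) with DESeq2, 1 (1) with limma-voom, 1395 (614) with the block, 706 (491) with the block in 6 libraries and 5049 (1217) without the third libraries. Between the compounds they were 450 (200) without a filter, 1 (1) with DESeq2, 14 (14) with the block, 36 (36) with the block in 6 libraries and 2081 (243) without the third libraries. For DMI against untreated they were 7970 (3126) without the third libraries. Leaving out the third libraries removes the widest library of each group, which narrows the spread by construction. Without a filter the median prior degrees of freedom of the fit rose from 4.58 to 317, so that single genes borrowed more from the rest; the cause of the other moves was not tested.

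Leaving out each library gave 1865 to 5569 genes (1261 to 2893 at least 2-fold) for DMI, 0 to 259 (0 to 162) for luteolin, 0 to 2646 (0 to 1223) for quercetin and 0 to 10 (0 to 7) between the compounds.

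Outside luteolin and DMI the replicate block rests only on a shared number: r was 0.068, 0.279 and 0.335 for quercetin, 0.079, 0.089 and 0.207 between compounds and 0.016, -0.014 and 0.022 for DMI against untreated, where the block called 4662 genes. For quercetin the block passed 9 of 15 panel genes and the block in 6 libraries 10, against 3 without it, Pparg and Cebpa among them in both. In none of the 4 comparisons did every library correlate best with its own number. Of the list calls by camera (17 for DMI, 15 for luteolin, 13 for quercetin, 8 between compounds), the block with the preset correlation and RLE scaling ended none, and fry kept 17, 0, 6 and 0. An estimated correlation kept 0 of each; with the block it kept 3, 1, 1 and 0, and without the third libraries 3, 8, 8 and 0. Fits of only the 6 libraries ended the aryl hydrocarbon receptor call for DMI (adjusted p = 0.0675) and the lysosome (0.109) and osteoblast (0.0584) calls for luteolin. Ranks ended the osteoblast calls for luteolin (0.0611) and quercetin (0.0533). Leaving out the third libraries ended the aryl hydrocarbon receptor call for DMI (0.234) and the interferon call for luteolin (0.805).

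Directions that turned were mostly of list tests near 0; the cause was not tested. With luteolin, aryl hydrocarbon receptor targets (medians -0.067 with the block, ranks and fry, -0.063 with the block in 6 libraries, -0.086 without the third libraries, -0.112 to -0.034 leaving out each library), NRF2 targets (-0.069, -0.054, -0.08, -0.182 to 0.028), Wnt (-0.06 by ranks, -0.218 to 0.126), matrix genes (0.043 without the third libraries, -0.244 to 0.059) and glucocorticoid response (-0.251 to -0.036) turned. Interferon response turned to 0.029 with luteolin and 0.551 with quercetin without the third libraries, and for quercetin was 0.003 with the block in 6 libraries and ran from -0.506 to 0.502. With quercetin, aryl hydrocarbon receptor targets ran from 0 to 0.252, cell cycle from -0.14 to 0.078, NRF2 from -0.244 to -0.002 and glucocorticoid response from -0.43 to -0.019. Between compounds, cholesterol synthesis (-0.003 with the block, -0.1 to 0.145), inflammatory genes (-0.106 by ranks, -0.207 to 0.061), other cell type markers (-0.156 by ranks, -0.096 without the third libraries, -0.276 to 0.07), ATF4 (-0.081 to 0.091), cell cycle (-0.014 to 0.167), glucocorticoid response (0.029, 0.032 to 0.181) and muscle markers (0.399, -0.126 to 0.674) turned. Cebpb was 0.006 with luteolin by library totals (-0.21 to 0.082), 0.075 with quercetin (-0.339 to 0.212) and -0.282 between compounds (-0.259 to 0.276) without the third libraries, and Cyp1b1 ran from -0.272 to 0.063 between compounds.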

Other observations

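The tests of other splits were chosen after their results were seen; those of the third libraries, the lipogenic genes and the imprinted genes were written down before their values were computed, though the patterns came from these data.

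The third library of each induced group lay lowest on the untreated-to-DMI axis and had the lowest Pparg, Fabp4 and Scd1 levels of its group, though not the lowest Fasn level with quercetin. Thinning every library to the smallest total kept 1.005, 1.004 and 0.996 of the gap on the axis in DMI, luteolin and quercetin groups, which argues against depth. RNA like that of untreated cells mixed in would lower risen genes and raise fallen ones by one share; the shares from the risen and the fallen genes differed by 0.314, 0.389 and 0.589, with quartile ranges that did not overlap, which argues against it. A wrong label or a weaker induction of these cultures was not tested and stays open, and no biological explanation was tested, since the design names none.

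Lipogenic genes may have been lowered beyond what a lower position on the axis predicts. Over the 17 list members that rose with DMI, the median log2 difference left after subtracting the within-group slope on the axis was -0.234 with luteolin and -0.453 with quercetin, below the central 95% of 10000 random lists of risen genes (-0.049 to 0.179 and -0.039 to 0.261), and it ran from -0.45 to -0.205 and from -0.506 to -0.347 when each induced library was left out. This argues against lower differentiation alone under that slope. The slope rests largely on the third libraries, lipogenic genes move together so random lists understate the spread, and the unknown doses keep other explanations open.

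H19 and Plagl1, both imprinted, were among the 3 genes lower with luteolin, which raised the hypothesis that imprinted genes fell together. A list of 27 others, written from general knowledge before the test, had 18 tested members with a median log2 fold change of 0.062 with luteolin (6 lower, p = 0.316 by camera with an estimated correlation) and 0.217 with quercetin (5 lower, p = 0.367). The result was negative for these tested members, which were not lower as a set. The list left out Dlk1, which is also imprinted. With the replicate block Dlk1 stood at -0.595 with luteolin and 0.289 with quercetin (adjusted p = 0.334 and 0.388 by edgeR). With the block in only the 6 libraries it passed with luteolin (-0.594, adjusted p = 0.00285).

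The 6 libraries of each comparison can be split in 10 ways, too few for a share under 0.05. For DMI against untreated the real split called 4024 genes and 1926 at least 2-fold, and the highest other split 0; 1 of 10 splits gave as many. For luteolin, where the numbers were treated as pairs, the values were 3 and 3 against 0. The 3 other splits that part all pairs and the 6 that keep a pair gave 0 as well. For quercetin they were 150 and 114 against 1; for both compounds 1 of 10 splits gave as many. Between the compounds all 10 splits gave 0.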
